A study of Mus musculus with 8 samples.

How the data were processed

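The data are 8 gene expression arrays of mouse uterus, 4 from pregnant and 4 from pseudopregnant females, hybridised with biotin-labelled total RNA that was extracted with Trizol, per the labels. The sample titles give the group and call each sample a biological replicate. Whether animals of the 2 groups were mated, collected or hybridised on shared days is not given in the sources used here, so no batch could be tested. The values deposited by the authors are probe set intensities on a linear scale, made with RMA (background correction, quantile normalization between arrays and a median-polish summary per probe set), per the submitters' processing notes, which name RMA without a version. The software, its settings and the annotation build are not given in the sources used here. RMA usually ends on a log2 scale; the deposited intensities reached 8113 and had medians of 55.2 to 56.3, so log2 was taken here before any test, as had been laid down for that case. RMA makes the distributions of the arrays alike and compresses changes near the background, so small folds of dim genes are understated. No detection calls were used, and a probe set's intensity cannot be set against that of another probe set.

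The table held 35556 probe sets. The 6612 with the lowest identifiers formed a block of probe sets without any gene in the platform's gene table and were left out as array controls, an inference from that gap. Of the other 28944 probe sets, 21789 had 1 gene symbol, 1621 had several and 5534 had none listed; the latter 2 kinds were tested but never named. Gene numbers of 21698 of the 21789 matched the RefSeq gene table of the GRCm38.p6 assembly, and 0 had another symbol there. No coordinates are given, since the build of the array annotation is not named. A probe set was kept where at least 4 of 8 arrays lay above the 40th percentile of their own array, which left 17494 probe sets, 14328 of them with 1 symbol, for 13039 genes. A gene with several probe sets was represented by that with the highest mean over all 8 arrays, chosen without regard to group. Genes of families with close copies, such as Klra8, Lilr4b and Clec4a3, may share probes with their relatives, which the deposited values cannot separate.

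Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with a single group term, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all kept probe sets; a probe set with an adjusted p under 0.05 is said to have risen or fallen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, for lists of at least 5 measured genes, with the correlation estimated for each list and with fry as checks, each adjusted over the 28 lists tested. Means per array of the list members were compared by exact permutation tests over the 70 arrangements of 4 against 4 arrays, whose smallest two-sided p is 0.029. The same code, run on simulated values for 17494 probe sets of this comparison, of which 200 were changed, called 83% of the 1.5-fold and 96% of the 2-fold changes, with 4.28% false among its calls. It made 0 calls when no change was simulated, and it called 5 of 5 shifted lists and 0 of 15 unshifted ones. The simulated probe sets varied independently of one another, whereas the estimated correlation within a real list reached 0.63 for cell cycle genes. The simulation therefore does not give the rate of false calls in these data, of probe sets or of lists. Of the 319 probe sets called in these data, 74 reached a fold of 1.5. The share of smaller changes that would be called was not simulated.

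Before the data were examined, 31 lists with 605 genes were fixed: retinoid uptake, storage and synthesis; retinoic acid receptors, binding and breakdown; retinoic acid induced genes; genes responsive to progesterone or to estrogen; implantation and attachment; LIF and STAT3 targets; uterine glands; stromal decidualization; the hedgehog, Wnt and prostaglandin pathways; ion and water transport; epithelial junctions; interferon response; cell cycle; cholesterol synthesis; angiogenesis; stress genes; and markers of smooth muscle, epithelium, stromal fibroblasts, endothelium, mesothelium, macrophages and dendritic cells, neutrophils and eosinophils, lymphocytes and NK cells, adipocytes, red blood cells, ovary and oviduct, and blastocysts. Some genes stand in several lists, as Cyp26a1 does in the receptor, induced and progesterone lists. The array carried 558 of the 605, and 444 had a kept probe set. The rule for the genes named was fixed at the same time. It took the 10 largest rises and the 10 largest falls among probe sets past the threshold whose groups did not overlap and that had exactly 1 symbol of a named gene, up to 4 genes of each list with the smallest p, a core set of 25 retinoid and implantation genes whatever their p, and the gene of any array value far from its group. Areg, of the core set, had no probe set of its own in the gene table.

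The alternatives were median centring, cyclic loess and a repeated quantile normalization between arrays, no filter and a stricter filter (60th percentile), trend and robust variance in eBayes, array weights, the replicate number as a block, other thresholds, 1 probe set per gene, averaging the probe sets of a gene, scaling genes to unit SD for the list means, and leaving out each array in turn. Added after the data were seen were leaving out the 2 arrays farthest out on the main axis of variation, keeping only probe sets with 1 symbol, counting probe sets with identical values once, and the retinoid list means without Cyp26a1 and Lrat. The p-values measure the spread between the 4 samples of each group.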

Results

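Uteri of C57BL/6 mice, an inbred laboratory strain, were profiled on gene expression arrays on day 3 at 22 h, counting the night of mating as day 0. This is just before the time at which a blue dye injected into the circulation begins to mark the sites of embryo attachment. The pregnant group held 4 uteri of females mated with fertile males, in which no blue site was seen and from which blastocysts were flushed. The pseudopregnant group held 4 uteri of females mated with vasectomised males, which go through the hormonal changes of early pregnancy with no embryo present. Each array carried the total RNA of a sample labelled as a separate biological replicate. The submitters chose the samples for RNA quality, with RNA integrity numbers between 6.9 and 8.7 and absorbance ratios between 1.84 and 1.99 over the series. Median intensities lay between 55.2 and 56.3 on the 8 arrays, and correlations between arrays of a group lay between 0.984 and 0.994. The number of arrays, 4 in each group, limits the precision of every value below. The largest axis of variation, with 46.1% of the variance, separated the groups, and the pregnant replicate 2 array (-26.7) and the pseudopregnant replicate 1 array (20.3) lay farthest out on it. The other pregnant arrays lay between -6.6 and -4.9 and the other pseudopregnant arrays between 6.8 and 9.3.

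The comparison of pregnant with pseudopregnant uterus asks how the uterus responds to the presence of embryos before they attach. The males, fertile or vasectomised, differed between the groups as well, so an effect of the mating cannot be told apart from one of the embryos. The 10 largest rises in named genes were those of Cyp26a1, which breaks down retinoic acid, the cytotoxic lymphocyte genes Gzmb, Il2rb, Klra8 and Ncr1, the myeloid receptors Clec4a3 and Lilr4b, the magnesium channel Trpm6, the cell cycle regulator E2f8 and the leukocyte tetraspanin Cd53. Cyp26a1 was 4.39-fold higher in the pregnant group, with log2 intensities of 7.81 ± 0.66 against 5.67 ± 0.66 (SD, n = 4 each) and a limma adjusted p of 0.028. The other 9 rose by log2 differences between 0.85 for Cd53 and 1.51 for Gzmb, a size that is not exact for Lilr4b, whose pseudopregnant values lay below the 40th percentile of their arrays. Cyp26a1 lay below that line in pseudopregnant replicates 1 (5.31) and 2 (4.98), so its fold is not exact either. Part of the pseudopregnant values of Ncr1, Clec4a3 and Trpm6 lay below it as well. Among probe sets with 1 named gene, the largest falls were those of the small nucleolar RNAs Snora33, with a log2 difference of -1.86 ± 0.22 (SE), and Snord118, with -1.46 ± 0.18. The vault RNA Vaultrc5 (-0.69) and the small nucleolar RNA Snora74a (-0.52) followed, and then Kcne4, Krtap10-10, Rspo3, Mettl7a1, Fbxo32 and Pln, between -0.48 and -0.45. Of the 17494 probe sets kept, 319 changed (limma, adjusted p under 0.05), 247 of them higher and 72 lower in the pregnant group, and they held 193 and 47 named genes. The changes were small, with a median log2 difference of 0.43 among those that rose and -0.41 among those that fell. A fold of at least 2 was reached by 5 of the higher and 9 of the lower probe sets. At an unadjusted p under 0.05, limma had 4149 of the 17494 kept probe sets, 2499 higher and 1650 lower, where 874.7 are expected by chance. The share of higher calls was 77.4%, against 67.0% with each array centred on its median (193 higher, 95 lower) and 67.1% with a repeated quantile normalization (251 higher, 123 lower). The count fell to 84, 101, 207 and 86 without pregnant replicates 1, 2, 3 and 4, and to 40, 70, 40 and 235 without pseudopregnant replicates 1, 2, 3 and 4. In the same order, 12, 14, 20, 10, 7, 6, 8 and 21 of the 30 named genes past the threshold kept their calls.

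**Figure D1:**
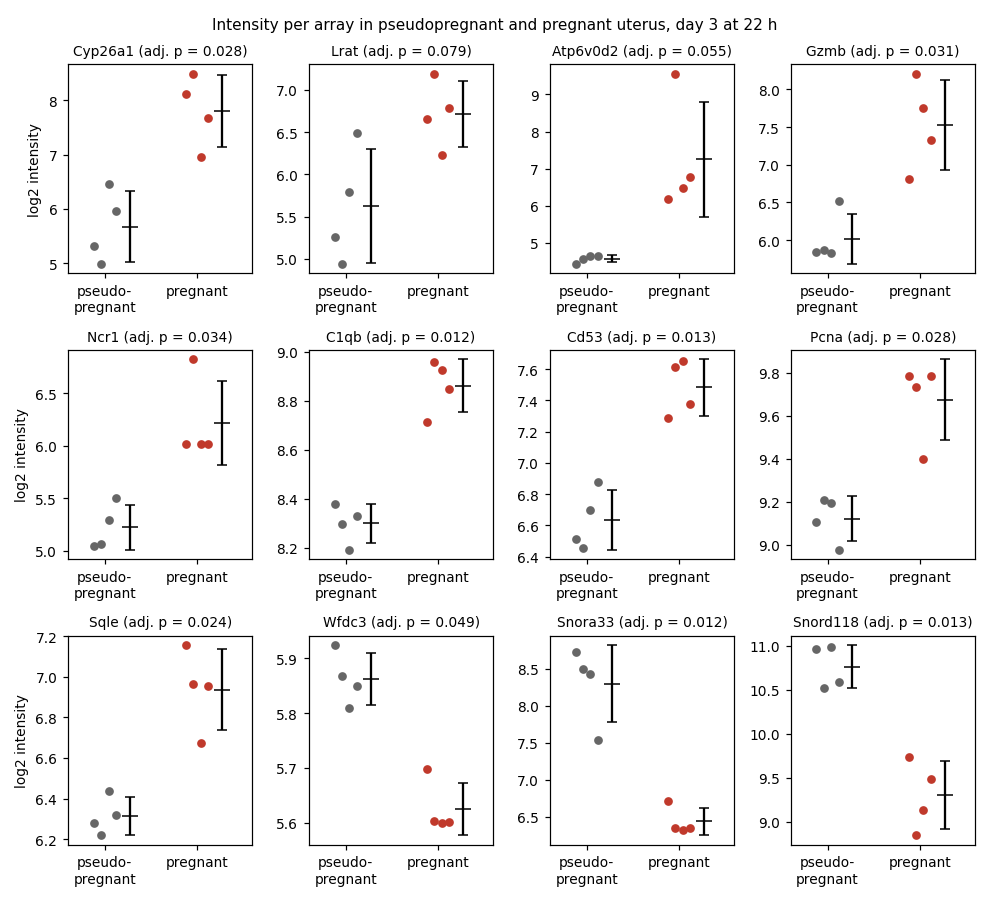
Log2 intensity of 12 genes on each array, by group. Points are single arrays (4 per group), horizontal marks and bars beside them are the group mean and SD, and the adjusted p from limma stands above each panel. The scale differs between panels. Cyp26a1, Gzmb, Ncr1, C1qb, Cd53, Pcna and Sqle were higher on every pregnant array than on every pseudopregnant array, and Wfdc3, Snora33 and Snord118 were lower on every pregnant array. Atp6v0d2 did not overlap between the groups either, but its adjusted p was 0.055. The values of Lrat overlapped.

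The title of the series names attenuated retinoic acid signalling as its subject, so the retinoid genes were followed in 3 lists. In the list of uptake, storage and synthesis genes, 0 of 18 measured members passed the threshold over all probe sets, and 1 was higher and 1 lower when adjusted over the list alone (limma; 4 higher and 4 lower at an unadjusted p under 0.05). Lrat, which stores retinol as esters, was higher by 1.09 ± 0.31 (SE, adjusted p = 0.079), with 6.71 ± 0.39 against 5.62 ± 0.67 (SD, n = 4 each), and passed without pseudopregnant replicate 4 (1.38, adjusted p = 0.038). Its values in pseudopregnant replicates 1 and 2 (5.26 and 4.94) lay below the 40th percentile of their arrays, so the size is not exact. Aldh1a1, an enzyme that makes retinoic acid, differed by -0.25 (adjusted p = 0.079), and Rdh10, which makes its precursor retinal, by -0.30 (adjusted p = 0.12). The retinol carrier Rbp4 differed by 0.25 (adjusted p = 0.11), the retinol receptor Stra6 by 0.26 (adjusted p = 0.14) and the retinal reductase Dhrs3 by -0.22 (adjusted p = 0.14). Adh1 differed by -0.04 ± 0.091 (SE, adjusted p = 0.83) and Aldh1a2 by 0.11 ± 0.11 (0.56), with -0.11 to 0.04 and 0.012 to 0.16 without single arrays. Aldh1a3 and the binding protein Crabp2 lay below the intensity filter.

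Among the receptors, binding proteins and breakdown enzymes, 1 of 15 measured members rose, Cyp26a1. Adjusted over the list alone, Cyp26a1 was higher and its relative Cyp26c1, at -0.26 (0.077 over all probe sets), was lower. The receptor Rara differed by 0.03 ± 0.052 (SE, adjusted p = 0.75; -0.0033 to 0.055 without single arrays), Ppard by 0.21 (adjusted p = 0.11) and the corepressor Nrip1 by -0.17 (adjusted p = 0.18). Among the genes known to be induced by retinoic acid, 1 of 21 measured members rose, again Cyp26a1, with the same count adjusted over the list alone, and 14 of 21 had differences below 0. The adjusted p of Cyp26a1 lay between 0.022 and 0.085 over 17 alternatives. Its call ended with the replicate number as a block and without the intensity filter (0.056). It also ended without pregnant replicate 1 (0.060), 2 (0.050, just above the threshold) or 4 (0.059) or pseudopregnant replicate 1 (0.085) or 2 (0.056), while its log2 difference stayed between 1.90 and 2.42.

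The mean over the members of each list, taken per array, was compared with exact permutation tests over the 70 arrangements of the arrays, in which the smallest two-sided p is 0.029. The mean of the induced genes was 0.11 higher in the pregnant group, 7.18 ± 0.038 against 7.07 ± 0.043 (SD, n = 4 each), with no overlap between groups (exact permutation p = 0.029, and 0.086 when adjusted over the 3 lists). The mean of the receptor and breakdown list was 0.10 higher (exact permutation p = 0.057, adjusted 0.086), and that of the synthesis list differed by 0.03 (exact permutation p = 0.51; 0.055 without pregnant replicate 2, -0.00038 without pregnant replicate 4). These means differ in sign from the medians of the members, which were -0.10, -0.05 and -0.03, and from the rank of the lists among all genes, where camera gave a downward direction with adjusted p of 0.33, 0.55 and 0.69. Without Cyp26a1 and Lrat, an alternative chosen after seeing the data, the difference of the induced genes turned to -0.05 (exact permutation p = 0.029), and those of the other lists to -0.04 (0.14) and -0.04 (0.54). With the stricter filter the difference of the induced genes was 0.23 (exact permutation p = 0.029). With each gene scaled to unit SD the difference of the induced genes was -0.29 (exact permutation p = 0.057), and without single arrays its p was 0.057 except without pregnant replicate 3 (0.029).

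**Figure D2:**
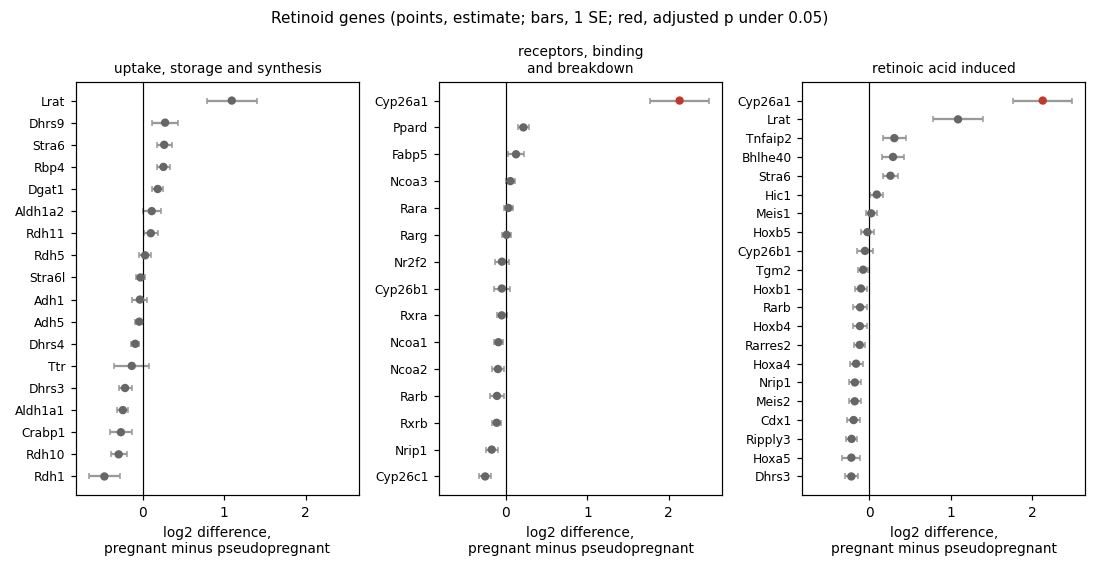
Log2 difference, pregnant minus pseudopregnant, of the measured members of the 3 retinoid lists (18, 15 and 21 genes). Points are limma estimates, bars are 1 SE (4 arrays per group) and red marks an adjusted p under 0.05. Cyp26a1, at 2.13, is the member past the threshold and appears in 2 lists, and Lrat, at 1.09, lies apart from the other genes, most of which lie near 0.

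Of 16 measured macrophage and dendritic cell markers, 10 rose over all probe sets and 13 adjusted over the list alone, and all 16 had differences above 0, with a median of 0.44. The complement genes C1qb and C1qc rose by 0.56 ± 0.068 (SE, adjusted p = 0.012) and 0.45 ± 0.084 (adjusted p = 0.036). The macrophage surface receptor Adgre1 rose by 0.62 ± 0.099 (adjusted p = 0.025) and the integrin Itgax by 0.57 ± 0.11 (adjusted p = 0.035). The mean per array was 0.41 higher, with no overlap of groups (exact permutation p = 0.029, adjusted over 31 lists 0.11). Of the 31 lists, 8 reached this smallest p. Of 8 measured lymphocyte and natural killer (NK) cell markers, 4 rose, and 6 adjusted over the list alone. These were genes of cytotoxic cells, namely the granule proteases and pore protein Gzmb (1.51 ± 0.27) and Prf1 (0.42 ± 0.085) and the receptors Il2rb (1.10 ± 0.20) and Ncr1 (0.99 ± 0.18). The mean per array was 0.65 higher (exact permutation p = 0.029, adjusted over 31 lists 0.11). The T cell genes of that list, Cd3e and Cd3g, differed by -0.15 ± 0.084 (adjusted p = 0.30) and 0.04 ± 0.18 (0.90). Camera placed both lists above the other genes, with adjusted p of 1.1e-10 and 0.00088 at the preset correlation of 0.01, but both calls were lost with an estimated correlation (adjusted p = 0.35 and 0.57 with an estimated correlation). Pregnant replicate 2, the array farthest from its group, had the highest mean of both lists, and without it the macrophage count was 3 of 16 and the lymphocyte count 2 of 8. Without pregnant replicates 1, 3 and 4 the macrophage counts were 3, 3 and 2 and the lymphocyte counts 2, 1 and 0, and without pseudopregnant replicates 1, 2, 3 and 4 they were 1, 1, 1 and 5 and 0, 0, 0 and 5. Without the intensity filter 1 macrophage marker and 0 lymphocyte markers rose.

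All 29 measured cell cycle genes had differences above 0, with a median of 0.35, but 1 of them rose over all probe sets and 6 adjusted over the list alone. The replication factor Pcna rose by 0.55 ± 0.094 (SE, adjusted p = 0.028), and the helicase subunits Mcm5 (0.43, adjusted p = 0.055), Mcm4 (0.47, 0.057) and Mcm2 (0.35, 0.064) did not pass. Camera gave an adjusted p of 2.6e-07, which became 0.57 with an estimated correlation, and the mean per array was 0.35 higher (exact permutation p = 0.029). Pregnant replicate 2 had a mean of 7.86 over this list, against 7.19 to 7.28 on the other pregnant arrays and 6.89 to 7.15 on the pseudopregnant arrays, and without it the difference of the means was 0.19. Of 20 measured genes of cholesterol synthesis, 3 rose, and 7 adjusted over the list alone. They were the enzymes Sqle (0.62 ± 0.095, adjusted p = 0.024), Cyp51 (0.71 ± 0.11, 0.024) and Hsd17b7 (0.39 ± 0.069, 0.030), while Idi1 (0.66, 0.058) missed the threshold. Camera gave an adjusted p of 0.0010, which became 0.57 with an estimated correlation, and the mean per array was 0.21 higher (exact permutation p = 0.057). Without pregnant replicates 1, 2, 3 and 4 the cholesterol count was 1, 2, 5 and 0, and without pseudopregnant replicates 1, 2, 3 and 4 it was 0, 0, 1 and 2. The cell cycle count was 0 without pregnant replicate 1 or 4 or pseudopregnant replicate 1, 2 or 3, and 5 without pregnant replicate 3. Pcna itself passed under 9 of 17 alternatives. Among the others, it lost its call without the filter (0.058), without pregnant replicates 1 (0.059), 2 (0.052) or 4 (0.064) and without pseudopregnant replicates 1 (0.077), 2 (0.055) or 3 (0.064). The 5 without pregnant replicate 3 were Pcna and 4 further genes, among them Mcm5 (0.036), Mcm4 (0.033) and Mcm2 (0.039), and Idi1 (0.022) passed without that array as well. At an unadjusted p under 0.05, limma put 14 of the 29 cell cycle genes higher with all arrays.

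Among genes tied to implantation, Atp6v0d2, a subunit of the vacuolar proton pump, differed by a log2 value of 2.67, with 7.25 ± 1.56 against 4.58 ± 0.10 (SD, n = 4 each), and did not pass (adjusted p = 0.055). Its pseudopregnant values, 4.44 to 4.65, lay below the 40th percentile of their arrays, 5.24 to 5.32, as did those of Gjb2 (4.48 to 5.31), so the sizes of these differences are not exact. Its value in pregnant replicate 2 was 9.555, against 6.18 to 6.78 on the other pregnant arrays, and without that array the difference was 1.90 with an adjusted p of 0.00080, within a range of 0.00080 to 0.13 over 16 alternatives. The gap junction gene Gjb2 differed by 1.19 ± 0.26 (SE, adjusted p = 0.052), Itgav by 0.29 (0.058), the Wnt inhibitor Dkk1 by -0.32 (0.064), the homeobox gene Msx1 by -0.61 (0.0998) and the growth factor Bmp2 by 0.99 ± 0.42 (0.19). Without pregnant replicate 2 Bmp2 differed by 0.49, and without pregnant replicate 3 Gjb2 differed by 1.45 and passed (0.022). It also passed with cyclic loess (0.047), a repeated quantile normalization (0.0499), array weights (0.045) and averaged probe sets (0.048). Of 24 measured members of the implantation and attachment list, 0 passed over all probe sets, and 5 were higher and 2 lower adjusted over the list alone (limma; 8 and 2 at an unadjusted p under 0.05). The mean per array of that list was 0.23 higher (exact permutation p = 0.029), and camera gave 0.25 (0.044 without the filter). The cytokine Lif, which is required for implantation in mice, differed by -0.24 ± 0.21 (adjusted p = 0.52), Hbegf by 0.12 ± 0.081 (0.41; 0.060 to 0.18 without single arrays), Ptgs2 by 0.23 ± 0.37 (0.74) and Hand2 by 0.14 ± 0.13 (0.54). Without pregnant replicate 2 Lif differed by -0.03 and Hand2 by -0.01, and without pseudopregnant replicates 1 and 4 Ptgs2 differed by -0.02 and -0.05. Lif lay below the 40th percentile of the array in pregnant replicates 2 (4.59) and 3 (5.19). Dkk1 did so in pregnant replicates 2, 3 and 4, and Ptgs2 in pseudopregnant replicates 1 and 4. The sizes for these genes are therefore not exact either.

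The progesterone receptor Pgr differed by 0.03 ± 0.071 (SE, adjusted p = 0.81) and the estrogen receptor Esr1 by -0.07 ± 0.052 (0.43), with -0.0092 to 0.080 and -0.094 to -0.043 without single arrays. Of 22 measured progesterone-responsive genes 1 rose, Cyp26a1, with 1 higher and 1 lower adjusted over the list alone, and Gata2 differed by -0.32 (0.062), Ihh by -0.30 ± 0.23 (0.46; -0.04 without pregnant replicate 2) and Hoxa10 by -0.02 ± 0.062 (0.86; -0.048 to 0.030 without single arrays). Of 21 measured estrogen-responsive genes 0 passed and 1, Gjb2, was higher adjusted over the list alone. Muc1 differed by -0.34 (0.12; -0.21 without pregnant replicate 2) and Ltf by -0.15 ± 0.21 (0.69), with -0.34 to -0.00054 for Ltf without single arrays. Camera gave adjusted p of 0.46 and 0.58 for these lists. Of 13 measured gland genes, 1 fell, Wfdc3, by -0.24 ± 0.051 (0.049), and its call ended whichever array was left out and under 14 of 16 alternatives (adjusted p 0.047 to 0.12). The gland proteases Prss28 (1.78 ± 0.65) and Prss29 (1.74 ± 0.63) were 3.45-fold and 3.34-fold higher on average and did not pass (0.14 each), and without pregnant replicate 2 their differences were 1.04 and 1.09. Of 16 measured genes of stromal decidualization, the change of stromal cells that follows attachment, 0 passed, and the mean per array was 0.20 higher (exact permutation p = 0.029, camera 0.058), and 0.11 without pregnant replicate 2. Its camera p passed without pregnant replicates 1 (0.015), 3 (0.046) and 4 (0.036) or pseudopregnant replicate 1 (0.036), without the filter (0.0083) and with trend and robust variance (0.046). Gja1 differed by 0.51 (0.068) and Alpl by 0.70 (0.12), and without that array Alpl differed by 0.40 and passed (0.038).

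All but 1 of the 15 measured stromal fibroblast markers were above 0 (camera adjusted p = 0.0032 upward, 0.57 with an estimated correlation, 0.051 without pregnant replicate 2 and pseudopregnant replicate 1 together), led by Thy1 (0.25, adjusted p = 0.060) and Vcan (0.37, 0.066; 0.046 without pregnant replicate 3). Of 15 measured endothelial markers, 13 were below 0 (camera 0.0024 downward, 0.57 with an estimated correlation), led by Tie1 (-0.30, 0.083) and Erg (-0.23, 0.11). Of 24 measured genes of epithelial junctions, 17 were below 0 (camera 0.024 downward, 0.57 with an estimated correlation), led by Cldn3 (-0.44, 0.12). With all arrays and the main settings none of these members passed over all probe sets, and 2 stromal markers were higher adjusted over the list alone (limma; at an unadjusted p under 0.05, 6 stromal markers were higher and 5 endothelial and 3 junction genes lower). Thy1 and Vcan each passed under 2 of 17 alternatives (lowest limma adjusted p 0.044 and 0.046). The junction call ended without pregnant replicate 2 (0.091), whose mean of 6.59 lay below the 6.75 of each of the other pregnant arrays, and without pseudopregnant replicate 1 (0.068), within a range of 0.0085 to 0.57 over 20 alternatives. It ended as well with cyclic loess or a repeated quantile normalization (0.060 each), without the filter (0.087), with the stricter filter (0.062) and with array weights (0.053). The difference of the mean per array was 0.14 for stromal, -0.13 for endothelial (exact permutation p = 0.029 each) and -0.08 for junction genes (0.086). Without pregnant replicate 2 that of the junction genes was -0.04.

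**Figure D3:**
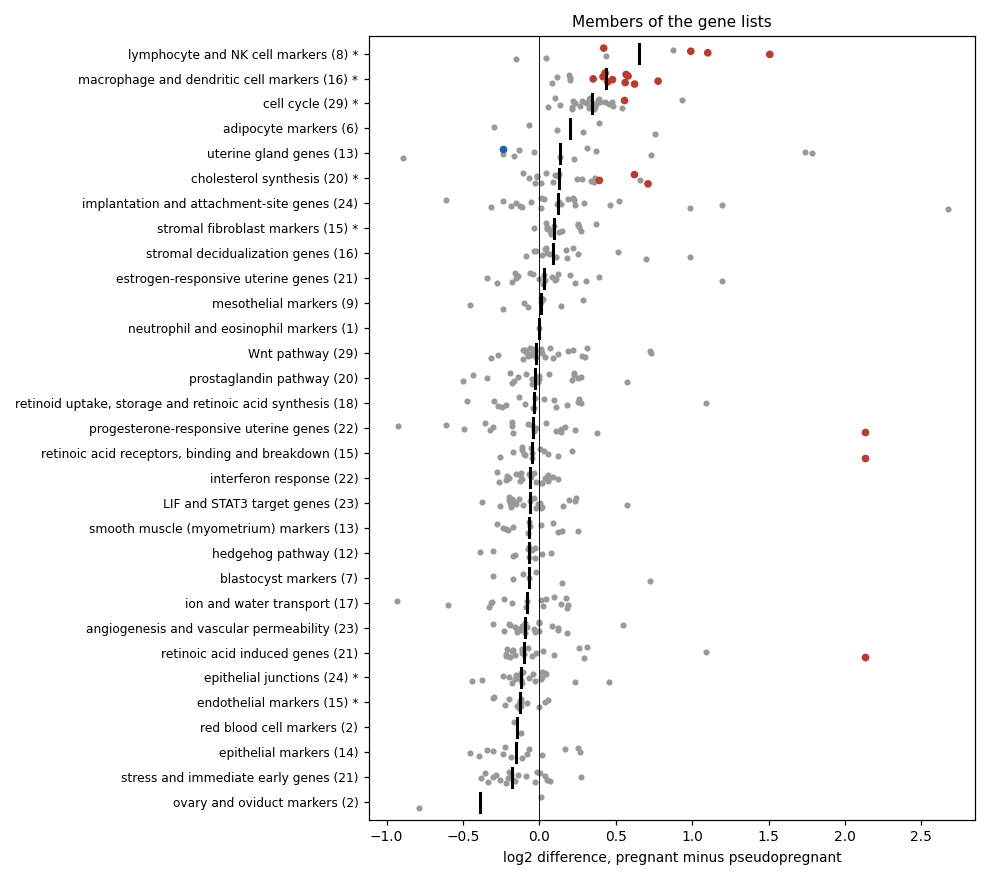
Log2 difference, pregnant minus pseudopregnant, of the measured members of 31 gene lists, with the number of members in brackets. Each point is a gene, red or blue where it rose or fell at an adjusted p under 0.05, black bars are list medians and an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Lymphocyte, macrophage and cell cycle genes lie farthest to the right, with medians of 0.65, 0.44 and 0.35.

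Epithelial markers (median -0.15 over 14 genes, camera adjusted p = 0.095) and smooth muscle markers (-0.07 over 13, 0.083) were not past the threshold, although 5 smooth muscle markers, led by Myh11 (-0.22, 0.070), were lower adjusted over the list alone. The smooth muscle list passed under 7 of 20 alternatives, within a range of 0.00080 to 0.62. Among these were the fits without pregnant replicate 2 (0.026), without pseudopregnant replicate 1 (0.0057) and without both (0.00080). The other lists were not past the threshold either, with camera adjusted p of 0.32 for LIF and STAT3 targets, 0.16 for hedgehog, 0.98 for Wnt, 0.51 for prostaglandin, 0.15 for ion and water transport, 0.12 for interferon response, 0.11 each for angiogenesis and for stress genes, 0.58 for mesothelial, 0.95 for adipocyte and 0.55 for blastocyst markers. Of these, the interferon list passed without pregnant replicate 3 (0.0092) or pseudopregnant replicate 1 (0.021) or 2 (0.048). The stress list passed without pregnant replicate 3 (0.018) or pseudopregnant replicate 1 (0.019), without both extreme arrays (0.034) and with array weights (0.047), and the angiogenesis list with the stricter filter (0.011). The epithelial list passed without pregnant replicate 3 (0.046) or pseudopregnant replicate 4 (0.019). In the prostaglandin list 4 genes were higher and 3 lower adjusted over the list alone, among them Hpgds (0.57, 0.066) and the receptor Ptgfr (-0.43, 0.061). Adjusted over the list alone, 1 gene was higher in each of the angiogenesis (Pgf, 0.55) and blastocyst (Eomes, 0.72, not exact because its pseudopregnant values lay below the 40th percentile of their arrays) lists, and 1 lower in each of the adipocyte (Plin4, -0.30) and ovary and oviduct (Inha, -0.79) lists. Over all probe sets, Hpgds passed without pseudopregnant replicate 4 (0.017), Inha without pseudopregnant replicate 2 (0.045), Pgf without pregnant replicate 3 (0.049) and Plin4 without pregnant replicate 1 (0.037). The neutrophil and eosinophil, red blood cell and ovary and oviduct lists, with 1, 2 and 2 measured genes, were too short for camera and had 0 members past the threshold. Over the 23 lists with no member past the threshold, limma had 81 of 323 genes at an unadjusted p under 0.05. That share is close to the one among all kept probe sets (4149 of 17494), so it does not set these lists apart. Camera at the preset correlation put 7 of 28 lists past the threshold, the estimated correlation 0 (1 at an unadjusted p under 0.05) and fry, which tests whether a list's genes move one way on balance, 1, the macrophage list (0.0094). The mixed form of fry, which tests for change in either direction, put 12 of the 28 past the threshold. Among them were the retinoid lists (0.0031 for synthesis, 0.0026 for receptors and breakdown, 0.0045 for induced genes). The mixed form asks whether members changed at all, not whether they changed more than the other genes measured. Cyp26a1 stands in the receptor and induced lists. These p-values therefore do not set the retinoid lists apart from other genes. Regrouping the arrays gave 7 or more lists in 13 of 35 splits, the actual grouping included, so the count of lists at the preset correlation is not beyond that of other groupings.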

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

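The tests of the marker lists without pregnant replicate 2, of macrophage against endothelial markers, of the median over small RNAs and of the epithelial markers in pregnant replicate 2 were chosen only after the result was seen. An array was singled out where its gap to the nearest of the other 3 arrays of its group took more of the group's range than Dixon's test allows at its 95% critical value, which chance gives in about 1 of 20 groups. This held in 20 of 334 groups of named genes and list means, where 16.7 are expected by chance. Pregnant replicate 2 held 8 of the 20, pregnant replicates 1, 3 and 4 held 4, 4 and 2, and pseudopregnant replicates 3 and 4 held 1 each.

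In pregnant replicate 2 the log2 intensities were 7.2422 for Klra8 (others 6.34 to 6.35), 6.8242 for Ncr1 (6.01 to 6.02), 9.9411 for Igfbp3 (8.54 to 8.64), 7.3028 for Alpl (6.05 to 6.23), 7.2357 for Sfrp1 (6.21 to 6.36) and 7.589 for Fzd6 (7.95 to 8.01). The list means of that array were 7.8612 for cell cycle genes and 6.5863 for epithelial junction genes. In pregnant replicate 3 the values were 5.7394 for Trpm6 (6.35 to 6.47), 6.6713 for Rbp4 (6.80 to 6.82), 9.3958 for Pcna (9.73 to 9.78) and 6.0356 for Idi1 (6.63 to 6.75). In pregnant replicate 1 they were 6.7158 for Snora33 (6.33 to 6.35), 5.697 for Wfdc3 (5.60 on each other array), 6.1691 for Prf1 (6.31 to 6.32) and 6.0376 for Plin4 (5.77 to 5.81). Pregnant replicate 4 had 7.9174 for Fbxo32 (7.54 to 7.57) and 6.4026 for Inha (6.16 to 6.17). Pseudopregnant replicate 4 had 6.5141 for Gzmb (5.83 to 5.87) and pseudopregnant replicate 3 had 5.6757 for Klra8 (5.50 to 5.52).

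Of the macrophage and dendritic cell markers 10 of 16 rose in the pregnant uteri, and 4 of 8 lymphocyte and NK cell markers, all 4 of cytotoxic cells, with both camera calls lost at an estimated correlation (adjusted p = 0.35 and 0.57). Pregnant replicate 2 as the sole source is argued against, since without it the list means still differed by 0.37 and 0.5393, with each remaining pregnant array at least 0.21 and 0.14 above the highest pseudopregnant array. A lower share of the main tissue that would raise every other cell type alike is argued against for the macrophage markers. They and the endothelial markers moved apart by 0.5394 (exact permutation p = 0.029). The endothelial list, picked for this after the results were seen, itself differed by -0.13, so an uneven shift among cell types stays open. More blood left in the pregnant uteri is argued against for the same markers because the mean of 4 globin probe sets differed by -0.2694, with a within-group SD of 0.23, where the macrophage mean differed by 0.41. More of these cells in the wall, more transcript in each, the presence of embryos and the mating with fertile males stay open, as untested.

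Snora33, Snord118, Vaultrc5 and Snora74a were lower in the pregnant uteri, and Snora75, named after its values were seen, was higher by 0.45 ± 0.081 (SE, adjusted p = 0.034). The median over 51 probe sets for small nucleolar, Cajal body and vault RNAs was -0.07923 (SD 0.38), against -0.69 among the 5 past the threshold. Those 5 were picked from the 51 for passing, so their median lies farther from 0 by selection. Whether small RNAs were recovered less well in the pregnant samples is therefore not decided. Of the 51, 33 were below 0, and at an unadjusted p under 0.05 limma had 12 lower and 3 higher. Snora33 and Snord118 lie in or at the genes Rps12 and Tmem107. The mRNA of these differed by -0.3128 ± 0.087 (SE, limma adjusted p = 0.078) and -0.09 ± 0.082 (0.53), against -1.86 and -1.46 for the small RNAs. An equally large fall of that mRNA is argued against. The arrays measured the amount of mRNA and not transcription, so lower transcription as the source is not decided. A loss that depends on the length or structure of an RNA, the presence of embryos and the mating with fertile males stay open, as untested.

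Pregnant replicate 2 lay apart from the other pregnant arrays. Its deviation from them correlated at 0.1989, across probe sets, with the change that the other 3 shared, where the same measure was -0.46 to -0.41 for each of the others. The mean of the other 3 enters both sides with opposite sign, which pushes this measure below 0. For the others that mean also held pregnant replicate 2, so their values are no neutral baseline. The value of 0.1989, above 0 despite that push, goes with an array farther along the change from pseudopregnant to pregnant. Less epithelium in the tissue taken cannot be told apart from this, since 9 of 14 epithelial markers (64.29%) were lowest in that array, between the bounds of 25% and 75% set for the test. The stage and the number of the embryos, and how the tissue was taken, stay open, as untested.

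Over the 35 splits of the 8 arrays into 4 and 4, 1 gave at least as many changed probe sets as the actual grouping, the actual grouping itself. It had 319, against a highest count of 0 in any other split. A share of 1 in 35 is the smallest that these splits allow. Every other split mixed the 2 groups, which adds their difference to the spread, so the counts of 0 do not exclude chance. For the number of gene lists past the threshold chance cannot be excluded, since 13 splits gave 7 or more and the highest of the others gave 12. List by list, a camera p as small came up in 1 of 35 splits for macrophage, 3 for endothelial, 4 for lymphocyte and NK cell, 5 each for cholesterol and stromal, 10 for junction and 14 for cell cycle genes.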

How the results depend on the processing

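Leaving out both arrays farthest out on the main axis, leaving out Cyp26a1 and Lrat, keeping only probe sets with 1 symbol and counting identical probe sets once were chosen only after the result was seen. The direction of the 30 named genes that passed was kept in each alternative that measured them (18 under the stricter filter). Of these, 29 or 30 kept their call under the 3 other scalings, trend and robust variance, array weights and averaged probe sets, 8 without a filter, and 6 to 21 without single arrays. Genes near the background, such as Crabp2, are limited by the signal of the array and were not tested.

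The number of changed probe sets, 319 (247 higher, 72 lower), was 54 (42 and 12) without a filter, 708 (523 and 185) with trend and robust variance, 1544 (1049 and 495) at an adjusted p under 0.1 and 74 (58 and 16) with a fold of at least 1.5. It was 166, with 109 higher, at an unadjusted p and that fold, and 48 (35 and 13) without both extreme arrays. The lower calls were 123 with cyclic loess, 123 with a repeated quantile normalization and 120 with array weights, while the higher calls stayed within 1.5 times. Without single arrays the count was 40 to 235 (27 to 170 higher, 12 to 82 lower). Of the calls, 48 of the 54 without a filter, 315 of the 708 and 42 of the 48 were among the 319. A lower threshold or an added fold changes the count by construction, and fewer arrays weaken the test. For the filter, the variance model and the scalings the cause was not tested. Under 8 further choices (the scalings, the stricter filter, array weights and how probe sets are counted) the total was 266 to 437.

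The lists past the threshold, 7, numbered 0 with an estimated correlation, 1 with fry and 7 to 11 without single arrays. The mean of the retinoic acid induced genes, 0.11, was 0.09025 with centred arrays, 0.0953 with repeated quantile normalization and 0.08088 without a filter (exact permutation p = 0.057 each), and 0.2328 with the stricter filter (0.029). It was -0.2913 with genes scaled to unit SD and -0.04986 without Cyp26a1 and Lrat, where the large share of Cyp26a1 in the mean is removed by construction. Without single arrays it was 0.09569 to 0.1267. The mean of the receptor and breakdown list reached 0.1689 with the stricter filter (exact permutation p = 0.029). That filter kept Cyp26a1 and dropped dimmer members, such as Cyp26c1 from this list and Ripply3 from the induced genes. The weight of Cyp26a1 in both means grew by construction, and how much of the larger differences this made up was not tested.

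With a replicate block, 174 probe sets were called (140 higher, 34 lower; 132 of them among the 319) and 11 lists passed. Of the 30 named genes 13 kept their call. Among the members, 2 macrophage and 1 lymphocyte genes rose, and Cyp26a1 had an adjusted p of 0.061. The lists gained were epithelial, interferon, stress and decidualization (0.042, 0.027, 0.0069 and 0.025). The mean of the induced genes was 0.1085 with an exact p of 0.125, the smallest that 4 pairs allow. Deviations of samples with the same number correlated at 0.245, 0.0162, -0.103 and 0.0442, and replicates 1 and 4 but not 2 and 3 correlated best with their own number. With 4 numbers this check neither shows nor excludes a pairing of the samples.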

Other observations

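The symbol families below were chosen only after the result was seen. The chaperonin that folds cytosolic proteins was followed by its subunits whose symbol is Cct and a number. All 7 measured subunits of that kind had differences above 0. Their mean per array was 0.19 higher in the pregnant group, without overlap (exact permutation p = 0.029, adjusted over 9 families 0.086). The difference was 0.15 to 0.18 under the 3 other scalings and 0.17 without pregnant replicate 2, and 1 subunit, Cct6a (0.34 ± 0.068, SE), passed over all probe sets. The 5 NK cell lectin-like receptors with a probe set of their own were all above 0, with a mean per array 0.75 higher (exact permutation p = 0.029, adjusted 0.086), 0.65 without pregnant replicate 2 and 0.74 to 0.79 under the other scalings, and 2 of them rose. Among 12 lectins of the Clec group 4 rose, the myeloid receptors Clec4a1, Clec4a3, Clec9a and Clec12a, by 0.76, 0.97, 0.81 and 0.59, while 7 lay below 0. The cytosolic ribosomal proteins differed by -0.055 over 57 genes (exact permutation p = 0.057), and by -0.073 to -0.088 under the other scalings (0.029 to 0.057). The proteasome subunits differed by 0.064 over 38 (0.057), and by 0.035 to 0.045 under the other scalings (0.11 to 0.23). The keratins differed by -0.096 over 13 (0.11) and the collagens by -0.015 over 41 (0.31), and by -0.084 to -0.11 and -0.020 to -0.034 under the other scalings.

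Several further genes gave values short of the threshold. Among ion and water transport genes, Fxyd4 differed by -0.93 ± 0.28 (SE, adjusted p = 0.096), the sodium pump subunit Atp1b1 by -0.60 ± 0.17 (0.079, and 0.047 without pseudopregnant replicate 4) and the water channel Aqp11 by -0.33 ± 0.11 (0.11). Of the interferon response genes, Zbp1 differed by -0.28, Ifit1 by -0.22 and Oasl2 by -0.21 (adjusted p = 0.13, 0.28 and 0.26), and without pregnant replicate 2 the latter pair by -0.14 each. In the hedgehog list, Hhip differed by -0.39 ± 0.31 (0.48) and Gli1 by -0.16 ± 0.12 (0.46), and without pregnant replicate 2 by -0.02 and -0.03. The Wnt inhibitor Sfrp1 differed by 0.72 ± 0.20 (0.081). Eomes, known from both trophoblast and NK cells, had an adjusted p of 0.057, with pseudopregnant values of 4.79 to 5.27, below the 40th percentile of their arrays.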
